A study of Homo sapiens with 6 samples.

How the data were processed

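Total RNA of BE(2)-C_tetoff_KDM4C cells was measured on 6 Affymetrix whole-transcript expression arrays, 1 RNA sample per array, 3 from cells grown with doxycycline and 3 from cells grown without it, all at day 6. Per the labels' protocols, RNA was isolated with Trizol, checked on a BioAnalyzer and a Nanodrop, and labelled with biotin through a terminal labelling kit for whole-transcript arrays. The design text calls the 3 samples of each group independent, without naming separate cultures or passages. The p-values of single probe sets therefore measure the spread between these samples.

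The deposited table held 1 log2 expression value per probe set and array, as processed by the authors. Per the submitters' processing notes, Partek was used, with no version. The background correction, the normalization, the summarization of probes and the genome build are not given in the sources used here. The log base was read from the values, which ran from 2.12 to 14.3. A scanner with 16-bit output cannot give a natural logarithm above 11.1 or a log10 above 4.82, which leaves log2. The medians of the 6 arrays lay between 3.94 and 3.96 and the upper quartiles between 6.16 and 6.20, so the arrays had been brought to a common scale, though not to identical distributions. Scanner intensities and detection calls were not used here. The number of arrays, and not a read depth, limits the precision, and no background level can be set for dim probe sets. Summarized array values are known to understate large fold changes.

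Probe sets were named through GEO's platform annotation. Of 53617 probe sets, 16098 had 1 gene symbol, 0 had several and 37519 had none in that table. The names covered 14884 genes, and all 16098 Entrez identifiers were found in the RefSeq gene table of GRCh38.p14, which changed 0 symbols. A probe set without a name is unnamed here, not without a gene. Genome positions are not given, because the build behind the probe sets is not stated. The lists of amino acid transporters (18 genes), replication-dependent histones, small nucleolar RNAs and mitochondrially encoded genes had 0 named probe sets and are not analysed here. The olfactory receptor list had 1, OR4C45, at a log2 difference of -0.05, and was not tested as a set. Several rows carry the name of a microRNA. Labelled long RNA was hybridised to them, and their values are reported as those of the row, not of a mature microRNA.

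All 53617 probe sets were fitted in R 4.3.3 with limma 3.58.1 (lmFit and eBayes), with the contrast no doxycycline minus doxycycline, no covariate and no filter on dim probe sets. P-values were adjusted by the method of Benjamini and Hochberg, and 0.05 was the threshold. Positive log2 differences mean higher without doxycycline. Errors are standard errors (SE) of the moderated fit or standard deviations (SD) of 3 arrays. A single value compared between 3 and 3 arrays in a two-sided exact permutation test cannot reach a p below 0.1. Where a gene had several probe sets, the one with the highest mean over all 6 arrays stood for it.

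Gene lists, the rule for named genes and the alternatives below were fixed before the data were examined. Of 35 lists, 30 had at least 2 measured members and were tested with limma's camera (preset correlation between genes 0.01) on 1 probe set per gene, with Benjamini-Hochberg adjustment over the 30 lists. Camera was repeated with an estimated correlation. Limma's fry, which tests whether the genes of a list move on balance in 1 direction, stood beside it. With the preset, camera's p rests on the spread between genes, with degrees of freedom set by their number. With an estimate, the degrees of freedom are those of the fit to 6 arrays, far fewer. The per-array means of the ATF4, mitosis and immediate early lists each gave an exact permutation p of 0.1, the smallest possible. The named genes were KDM4C and its paralogs, the 12 genes with the largest difference in each direction among genes past the threshold whose groups did not overlap, all genes of serine and glycine synthesis, and in every other list the 2 with the smallest p in each direction. Members beyond that rule are named where a small count of passing genes is spelled out or where the text says so. Of the 6 lists on amino acid metabolism and ATF4, the field in which the authors are known to have used these cells, none is independent evidence of its direction.

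The procedure was tested on simulated data with the means and moderated spreads of the real probe sets and a set of genes changed by known amounts. Moderated spreads are more alike between probe sets than the raw ones, so the recovery may be optimistic. At 3 arrays per group it recovered 20.9% of 67 genes changed by 0.5 on the log2 scale, 91.0% of 67 changed by 1 and 98.5% of 66 changed by 2, with 6 false calls among 146. In simulated lists, a shift of 0.3 of the mitosis list was found and 0 of 29 other lists were called. The simulated genes were drawn independently of each other, so the simulation cannot judge false calls of lists whose genes are correlated. In the real data the estimated correlation was as high as 0.303, for serine and glycine synthesis.

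The alternatives were the replicate number as a block, quantile normalization of the deposited values, median centring, leaving out the dimmer probe sets (mean below the median of all), an intensity trend with robust moderation, no moderation of the variances, array weights, each array left out in turn, stricter thresholds, named probe sets alone, and for the lists the mean of all probe sets of a gene. No 2 arrays were copies, since at most 0.067% of probe sets agreed within 0.0001 between any 2 of them. No label gives a scan date or batch.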

Results

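BE(2)-C is a human neuroblastoma cell line, and the derivative studied here carries a tet-off construct for KDM4C, a demethylase of methylated lysine 9 of histone H3. In a tet-off system doxycycline keeps the construct silent and its absence lets it be expressed. The comparison asks which transcripts change after 6 days with the KDM4C construct on. Expression was measured on 6 arrays, 3 from cells without doxycycline (construct on) and 3 from cells with doxycycline (construct off). No arrays of cells without the construct were analysed here, so every difference is that of KDM4C induction and doxycycline withdrawal together. Values are log2 expression values, and the correlation between arrays over all probe sets was 0.991 to 0.993 within groups and 0.990 to 0.991 between them. The first principal component took 29.1% of the variance and put the groups apart, at -23.5 to -22.7 with doxycycline and 21.0 to 24.7 without.

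KDM4C itself was 2.40-fold higher without doxycycline, at 9.03 ± 0.05 against 7.76 ± 0.05 (log2, SD, n = 3 each). The log2 difference was 1.27 (SE 0.07, limma adjusted p = 0.0079), and the direction is that of the labels in a tet-off system. The probe set does not separate the construct's transcript from the endogenous one. Of the paralogs, KDM4B was at 6.95 ± 0.13 against 6.90 ± 0.11, a difference of 0.05 with a 95% confidence interval of -0.17 to 0.28. KDM4A and KDM4D were at 0.55 (SE 0.12) and 0.28 (SE 0.11), and neither passed the test (limma adjusted p = 0.146 and 0.367). With 1 array fewer the KDM4C difference stayed between 1.24 and 1.29. Its limma adjusted p then rose to between 0.0597 and 0.0696 without doxycycline-treated replicate 1 or 2 or untreated replicate 2 or 3.

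**Figure D1:**
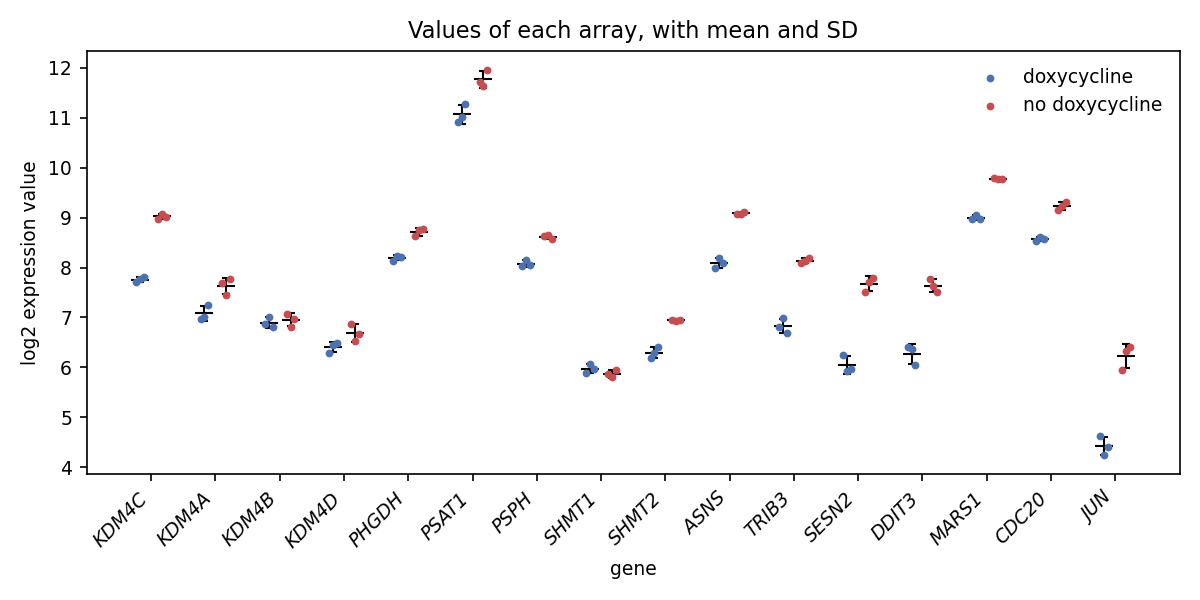
Log2 expression values of single genes (y axis) on each of the 3 arrays with doxycycline (blue) and the 3 without (red), with the mean and SD in black. KDM4C lay at a mean of 9.03 without and 7.76 with doxycycline, while the groups of KDM4B and SHMT1 overlapped.

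Among 53617 probe sets, 133 were higher and 50 lower without doxycycline at a limma adjusted p below 0.05. Of these 183, 86 had a gene name, 66 higher and 20 lower. The named genes with the largest increase past the threshold were CARTPT, a neuropeptide precursor (4.45-fold, log2 2.15, SE 0.27), and ULBP1, a ligand of the NKG2D receptor of natural killer cells (4.34-fold, log2 2.12, SE 0.17). They were followed by JUN, a subunit of the AP-1 transcription factor (3.49-fold), and SESN2, a stress-induced inhibitor of mTOR signalling (3.09-fold). The stress-response genes DDIT3, TRIB3 and DDIT4 were 2.58-, 2.48- and 2.47-fold higher, and TFPI2, a protease inhibitor, 2.56-fold. The 12 also held KDM4C and rows annotated to MIR7-3HG, MIR7-3 and MIR3143, at 2.70-, 2.65- and 2.69-fold. MIR7-3 lies in its host MIR7-3HG, so these rows are not independent. Of these 12, CARTPT varied most between replicates, with an SD of 0.59 without doxycycline against 0.05 with it.

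Among named genes past the threshold, the largest decrease was that of DCN, which encodes the matrix proteoglycan decorin, at 5.58 ± 0.10 without and 6.87 ± 0.04 with doxycycline (2.44-fold lower, log2 -1.29, SE 0.07, limma adjusted p = 0.0119). TM4SF4, a tetraspanin-like membrane protein, was 2.03-fold lower, and ARHGEF28 1.97-fold lower. PTGES (prostaglandin E synthase), REEP6, GPR155, IGFBP7, PARM1, GPR50 and SNX32 had log2 differences of -0.97, -0.96, -0.95, -0.84, -0.83, -0.81 and -0.80. Rows annotated to MIR548I2 and MIR548I1 completed the 12. Both belong to a multicopy microRNA family and are uncertain. The other MIR548I2 row was at 0.08, and the other MIR548I1 rows were at -0.36, -0.36 and -0.46, of the same sign as the one counted.

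All 183 probe sets had non-overlapping groups, which passing the threshold with 3 against 3 arrays makes nearly certain. Of all probe sets, 19.3% had such groups, where chance gives 10%. The count rests on all 6 arrays: leaving out 1 array left 1, 2 and 15 probe sets without doxycycline-treated replicate 1, 2 and 3, and 13, 0 and 0 without untreated replicate 1, 2 and 3 (limma, with 5542 to 6191 at an unadjusted p below 0.05).

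**Figure D2:**
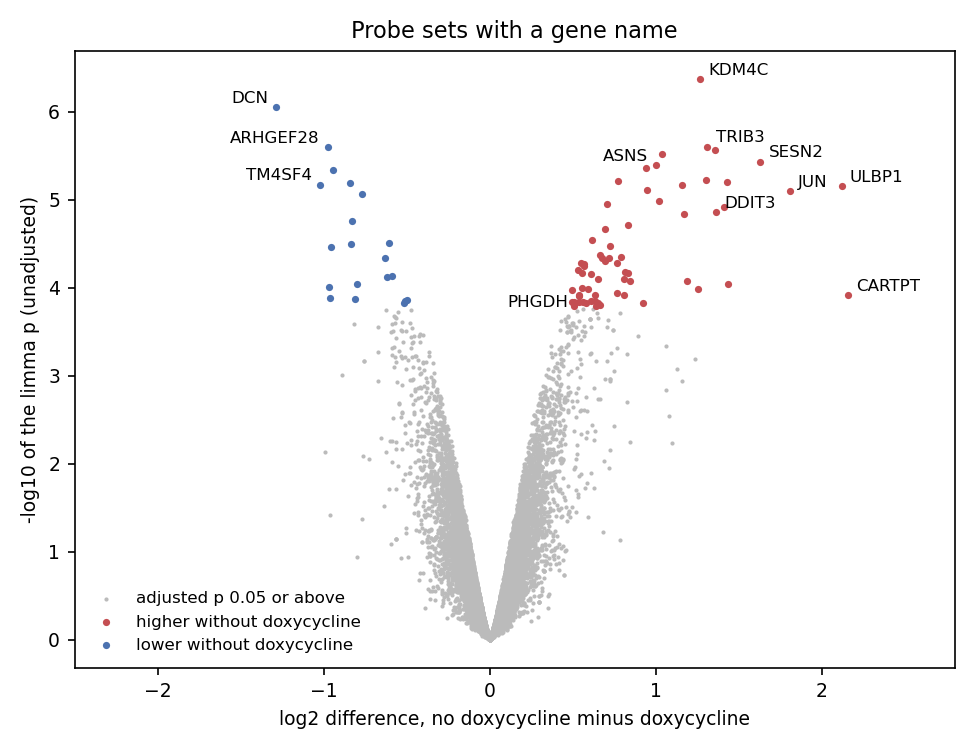
Log2 difference of each named probe set, no doxycycline minus doxycycline (x axis), against the -log10 of its unadjusted limma p (y axis). Red points (66) were higher and blue points (20) lower without doxycycline at an adjusted p below 0.05, with KDM4C at the top.

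Genes of the ATF4 stress response were higher without doxycycline, and smaller numbers of amino acid synthesis and tRNA synthetase genes passed the test. ATF4 is the transcription factor that induces amino acid synthesis and transport genes when amino acids are short. In the ATF4 and stress response list, all 14 measured genes had positive differences, 9 rose at an adjusted p below 0.05 (13 adjusted over the list alone) and 0 fell, with a median log2 difference of 1.03. SESN2, DDIT3, TRIB3, DDIT4, ATF5, GDF15 and STC2 rose by 1.16 to 1.63 on the log2 scale, and EIF4EBP1 and CTH by 0.53 and 0.51. ATF4 mRNA itself was at 0.31 (limma adjusted p = 0.179). Of the 5 genes of serine and glycine synthesis, PSPH (0.54, SE 0.07, 1.45-fold) and SHMT2 (0.65, SE 0.08, 1.57-fold) rose. PHGDH, the first enzyme of the pathway, was at 0.52 (SE 0.07, adjusted p = 0.0507) and PSAT1 at 0.69 (SE 0.13, adjusted p = 0.104), both with limma and both outside the threshold over all probe sets. With p adjusted over the list alone, 4 of the 5 rose, and SHMT1, the cytosolic isoenzyme of SHMT2, was at -0.11 (95% confidence interval -0.29 to 0.07). The camera call of this list was lost with an estimated correlation (adjusted p = 0.165).

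Of 11 other amino acid synthesis enzymes measured, ASNS (asparagine synthetase, 2.00-fold, log2 1.00, SE 0.07) and CTH (0.51) rose and 0 fell, with 6 higher adjusted over the list alone. CTH is also a member of the ATF4 list and is counted in both. OAT and PYCR3 were at -0.16 and -0.15. Of 17 cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, WARS1 (0.95, SE 0.08), MARS1 (0.77, SE 0.06) and GARS1 (0.62) rose and 0 fell. When adjusted over the list alone, 9 were higher and 1, RARS1 at -0.22, was lower. QARS1 was at -0.12, and the dimmer of the 2 WARS1 probe sets was at 0.42. The 9 folate one-carbon enzymes did not move together (median 0.04, mean -0.03, camera direction up, adjusted p = 0.848), with 1 higher and 1 lower adjusted over the list alone and 2 and 2 at an unadjusted p below 0.05. MTHFD1L and TYMS were at 0.42 and 0.15, and GCSH and MTHFD2L at -0.63 and -0.25, none past the threshold over all probe sets.

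With camera, the adjusted p was 2.66e-20 for the ATF4 list, 4.11e-05 for serine and glycine synthesis, 2.15e-04 for the other amino acid enzymes and 1.35e-07 for the tRNA synthetases. With an estimated correlation the ATF4 call held (adjusted p = 0.0160), while the others gave an adjusted p of 0.165, 0.0914 and 0.0914 in that order. The estimates were -0.003 for the ATF4 list and -0.040 for the other amino acid enzymes, below the preset 0.01. They were 0.303 for serine and glycine synthesis and 0.076 for the tRNA synthetases, above it. A higher correlation between genes therefore cannot account for the larger p of the ATF4 list and the other amino acid enzymes. With an estimate, camera also uses the far fewer degrees of freedom of the fit, which raises p by itself. The lists of this paragraph follow the authors' own field of work with these cells and are not independent evidence of their direction. With any 1 of the 6 arrays left out, 0 to 3 genes of the ATF4 list and 0 of the other lists passed singly.

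Genes of mitosis were higher without doxycycline. All 22 measured members had positive differences, with a median of 0.37, 6 rose and 0 fell (19 higher adjusted over the list alone). The 6 were CDC20, an activator of the anaphase-promoting complex (0.66, SE 0.07, 1.58-fold), PLK1 (0.63), KIF20A (0.57), HMMR (0.56), AURKB (0.55) and CCNB2, a mitotic cyclin (0.55, SE 0.06, 1.46-fold). Camera gave an adjusted p of 2.05e-20, and 0.0304 with an estimated correlation. In the list of 23 S phase genes 0 passed in limma (1 higher and 0 lower adjusted over the list alone, 3 and 1 at an unadjusted p below 0.05), the median was 0.04 and the camera adjusted p was 0.0835. That list passed with quantile normalization (adjusted p = 0.0467), with trend and robust moderation (adjusted p = 0.0483) and in fry (adjusted p = 0.0356), each time upward. CCNA2 and CDT1 were at 0.37 and 0.39, and CCNE2 and SLBP at -0.20 and -0.12. No mitosis gene passed singly with any 1 of the 6 arrays left out.

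Immediate early genes, which are induced within minutes of a stimulus, were also higher. All 10 measured had positive differences (median 0.43), 4 rose and 0 fell: JUN (1.81, SE 0.15), EGR1 (1.02, SE 0.09), FOS (0.84) and DUSP1 (0.57). Of the 10, 8 were higher adjusted over the list alone. Camera gave an adjusted p of 1.51e-10, and 0.0304 with an estimated correlation. That estimate was 0.004, below the preset 0.01, so a higher correlation between genes cannot account for the larger p. The fewer degrees of freedom with an estimate raise it here too. The second EGR1 probe set was at 0.43. IER3 was at 0.42 (limma adjusted p = 0.128), and its dimmer probe set, which does not stand for the gene, was at 0.49 and passed (limma adjusted p = 0.0417). With any 1 array left out 0 or 1 of the genes passed.

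No member of the cholesterol synthesis list (16 measured) or of the glycolysis and hypoxia list (14 measured) passed singly in the main fit. Among the alternatives, quantile normalization gave 1 higher cholesterol gene and leaving out dim probe sets gave 2. Trend with robust moderation gave 2 higher genes of glycolysis and hypoxia. Camera called both lists up, and both calls were lost with an estimated correlation (adjusted p = 0.138 and 0.188). Cholesterol synthesis had a median of 0.20 and a camera adjusted p of 2.23e-05. MVK and MVD, enzymes of the mevalonate pathway, were at 0.50 and 0.47, and TM7SF2 and MSMO1 at -0.28 and -0.07. The test adjusted over the list alone gave 7 higher and 1 lower, as did an unadjusted p below 0.05. Glycolysis and hypoxia had a median of 0.26 and a camera adjusted p of 5.83e-06. VEGFA, also a member of the ATF4 list, and NDRG1 were at 0.89 and 0.65, and HK1 at -0.03. In this list 4 were higher adjusted over the list alone, and 7 at an unadjusted p below 0.05.

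**Figure D3:**
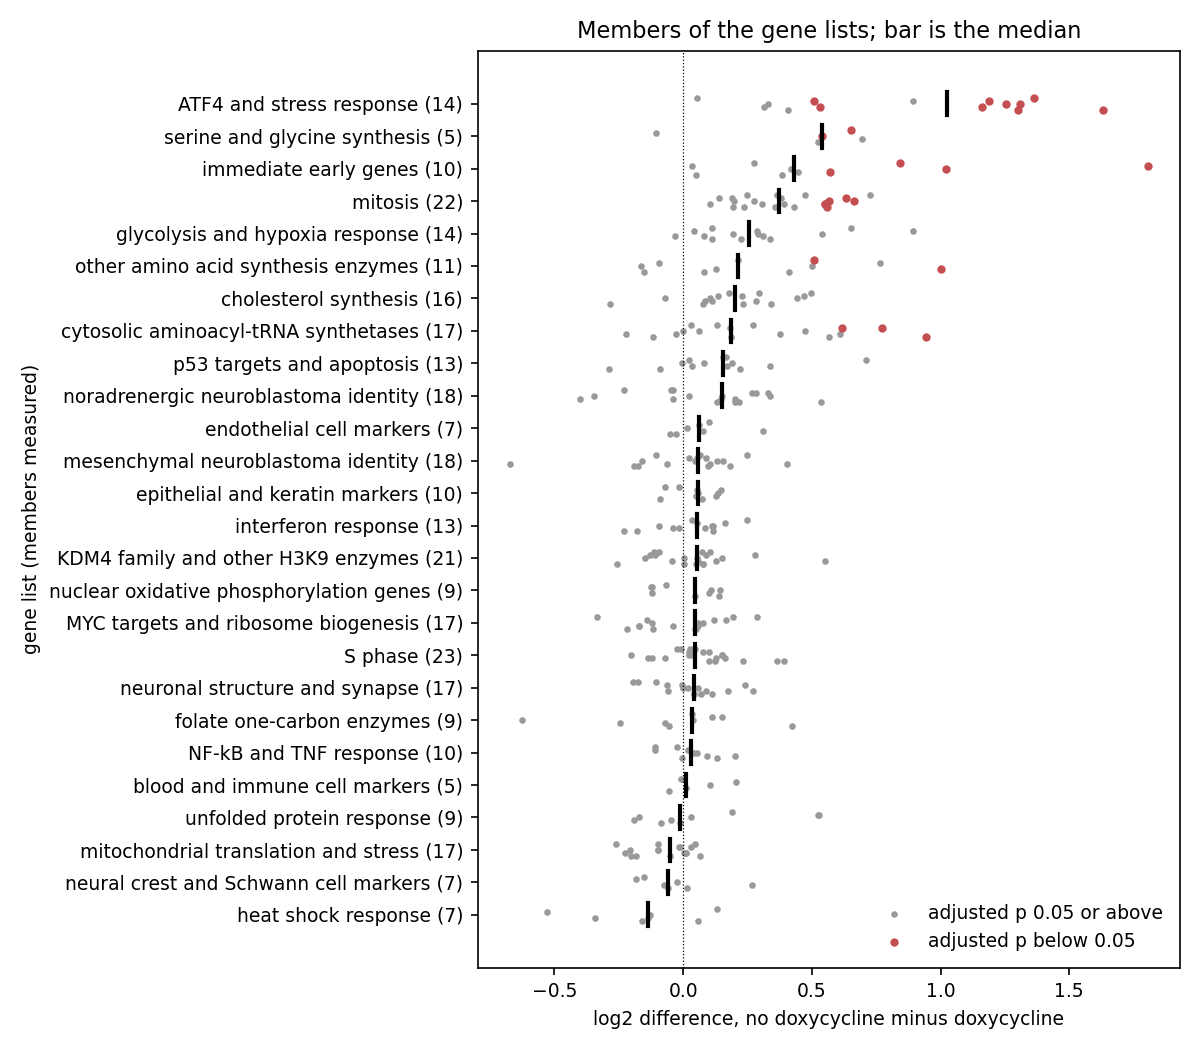
Log2 difference, no doxycycline minus doxycycline, of each measured member (points) of each gene list, with the list's median as a black bar and the number measured in brackets. Members past an adjusted p of 0.05 (red) lay in 6 lists, and the ATF4 list had the highest median, 1.03.

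Cell identity and the remaining stress programmes showed 0 genes past limma's threshold over all probe sets in the main fit. Without dim probe sets 2 unfolded protein, 1 p53 and 1 noradrenergic gene passed as higher. With trend and robust moderation 1 gene of each of these lists and 1 mesenchymal gene did, and with quantile normalization 1 noradrenergic gene. Of 18 genes of noradrenergic neuroblastoma identity, ALK and TH were at 0.54 and 0.34, and the granins CHGA and CHGB at -0.40 and -0.34 (camera adjusted p = 0.0829). Adjusted over the list alone, 6 were higher and 3 lower (7 and 3 at an unadjusted p below 0.05). The noradrenergic list passed upward with quantile normalization (adjusted p = 0.0452), with trend and robust moderation (0.0499), without doxycycline-treated replicate 3 (0.0365) and without untreated replicate 2 (0.0294). In the neuronal list of 17, VGF and MAP2 were at 0.27 and 0.24, and SYT1 and MAPT at -0.17 and -0.20. In the mesenchymal list of 18, SNAI2 and FOSL2 were at 0.40 and 0.25, and CD44 and VIM at -0.67 and -0.19. Most genes of the mesenchymal list lay below the median probe set, such as FN1 at 3.44 without and 3.39 with doxycycline, so a change could easily be missed. The mesenchymal list had 1 higher and 1 lower adjusted over the list alone. At an unadjusted p below 0.05 the neuronal list had 2 higher and 1 lower and the mesenchymal list 3 and 2. The 9 genes of the unfolded protein response had a median of -0.01 but a mean of 0.09, with XBP1 and ERN1 at 0.52 and 0.53 and the chaperone CANX and CRELD2 at -0.19 and -0.17. Camera gave that list the direction up, and 2 members, XBP1 and ERN1, were higher and 0 lower adjusted over the list alone (3 and 1 at an unadjusted p below 0.05). Heat shock genes (7) had a median of -0.14, with HSPA4L and HSPH1 at -0.53 and -0.34 and HSPB1 and BAG3 at 0.13 and 0.06 (0 higher and 2 lower adjusted over the list alone, 0 and 3 at an unadjusted p below 0.05). Of 13 p53 target and apoptosis genes, PMAIP1 and BAX were at 0.71 and 0.22, and CCNG1 and SESN1 at -0.29 and -0.09 (1 higher and 1 lower adjusted over the list alone, 2 and 1 at an unadjusted p below 0.05). The camera adjusted p was 0.549 for the mesenchymal and unfolded protein lists, 0.589 for the neuronal, 0.0835 for heat shock and 0.0991 for p53. Heat shock passed downward with trend and robust moderation (adjusted p = 0.0477), and in fry the neuronal and unfolded protein lists passed upward (adjusted p = 0.0285 and 0.0356).

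Of the markers of other cell types that a culture could hold, 0 passed limma's threshold, and SOX9 and ERG (3.59 without and 3.28 with doxycycline) had an unadjusted p below 0.05. The lists of neural crest and Schwann, epithelial, blood and immune, and endothelial markers had medians of -0.06, 0.06, 0.01 and 0.06 over 7, 10, 5 and 7 genes, with camera adjusted p of 0.709, 0.549, 0.647 and 0.549. TYROBP of the immune list lay at 3.35 in both groups and VWF of the endothelial list at 3.12 and 3.04, below the median probe set, while CD68 of the immune list lay above it, at 5.75 and 5.74. KRT18 was at 7.55 without and 7.43 with doxycycline, and SOX9 at 6.62 and 6.35. The dimmer KRT18 probe set had a log2 difference of -0.15, of the opposite sign.

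Camera called no shift of the remaining lists, and no array measured KDM4C binding or histone methylation at their genes. The 471 ZNF zinc finger genes had a median of -0.01 and a camera adjusted p of 0.732, with 0 genes past limma's threshold (32 higher and 29 lower at an unadjusted p below 0.05). ZNF732 and ZNF224 were at 0.55 and 0.38, and ZNF467 and ZNF770 at -0.58 and -0.47. The dimmer probe sets of ZNF224 and ZNF770 were at 0.03 and -0.19. The 16 clustered protocadherins had a median of -0.06 (PCDHB7 and PCDHB13 at 0.34 and -0.32) and the 10 cancer-testis genes -0.07, both with a camera adjusted p of 0.549. The 21 KDM4 and other H3 lysine 9 enzymes had a median of 0.05 (camera adjusted p = 0.647), with ATRX and CBX5 at -0.26 and -0.13. MYC targets (17), ribosomal proteins (48), nuclear oxidative phosphorylation (9), mitochondrial translation (17), interferon response (13) and NF-kB response (10) had medians of 0.05, -0.003, 0.05, -0.05, 0.06 and 0.03, with 0 genes past limma's threshold. The MYC list had a mean of -0.02, camera gave it the direction down, and 1 of its genes was lower adjusted over the list alone. At an unadjusted p below 0.05 they had, in that order, 2, 1, 0, 0, 1 and 0 higher and 2, 1, 0, 4, 1 and 0 lower. Their camera adjusted p values were 0.732, 0.844, 0.973, 0.103, 0.647 and 0.679, and mitochondrial translation passed downward in fry (adjusted p = 0.0186). NOLC1 of the MYC list was at -0.33, MRPS30 of the mitochondrial translation list at -0.26, IRF9 of the interferon list at 0.25 and RPS15 at 0.24. Most interferon genes lay below the median probe set, such as IFIT1 at 3.41 without and 3.59 with doxycycline.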

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

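With the replicate number as a block (replicate block), 0 probe sets were higher and 0 lower in limma, while 6251 had an unadjusted p below 0.05. The KDM4C difference stayed 1.27 with an adjusted p of 0.118, and the 8 list calls held (largest adjusted p 2.46e-04). The titles share only a number: same-numbered deviations from the group means correlated at -0.012, -0.014 and 0.041, and no-doxycycline replicates 1 and 2 did not correlate best with their own number. Leaving out dim probe sets gave 204 higher and 107 lower, trend with robust moderation 255 and 130, named probe sets alone 265 and 147 (fewer were tested). No moderation gave 7 and 4, and an adjusted p below 0.01 gave 3 and 0, with 53617 tested and 6664 at an unadjusted p below 0.05. Quantile normalization, median centring, array weights and the 1.5-fold limit stayed within 1.5 times the 133 and 50. With 1 array left out the counts were 0 to 12 higher and 0 to 3 lower, at 5542 to 6191 unadjusted; fewer arrays enter by construction. KDM4C was then 1.24 to 1.29. Estimated correlation gave 0.165 for serine and glycine synthesis and 0.0914 for both other amino acid enzymes and tRNA synthetases. The folate list gave 0.722 to 0.989 with 1 array left out, its sign changing. The 8 called lists held in every other alternative run, except cholesterol synthesis and glycolysis and hypoxia with an estimated correlation (0.138 and 0.188). Alternatives gained 11 list calls: S phase and noradrenergic identity with quantile normalization (0.0467, 0.0452), both and heat shock with trend and robust moderation (0.0483, 0.0499, 0.0477), noradrenergic identity without doxycycline replicate 3 or no-doxycycline replicate 2 (0.0365, 0.0294), and in fry S phase, neuronal, unfolded protein response and mitochondrial translation (0.0356, 0.0285, 0.0356, 0.0186). Lists without moderation were not run, since camera always moderates. PHGDH passed under quantile normalization (adjusted p = 0.0467), without dim probe sets (0.0390) and with trend and robust moderation (0.0203). Trend with robust moderation also gave 1 higher gene each in the folate, S phase and zinc finger lists. Causes were otherwise not tested. Signal over background is unknown, so small changes of dim probe sets cannot be judged.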

Other observations

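The tests on a doxycycline drug effect and on brightness, and the genes named in this paragraph, were chosen only after the results were seen. Among the other genes past the threshold, outside the fixed lists, were MYBL2 and FOXM1, transcription factors of mitotic genes (0.58 and 0.51, log2), the phosphatase CDC25C (0.63), the separase gene ESPL1 (0.69), TROAP (0.70) and KIF14 (0.53). The feedback inhibitors DUSP6 (0.72), SPRY2 (0.61) and SOCS1 (0.81), which damp growth factor and cytokine signalling, also rose, as did the Wnt antagonist DKK1 (0.83), the axon guidance receptor PLXNA2 (1.04) and GFRA3 (0.77), a co-receptor for a ligand of the GDNF family. Among the genes that fell were NPY2R, a receptor of neuropeptide Y (-0.77), CADPS, a factor of dense-core vesicle release (-0.63), and SEPTIN3 (-0.52). Of the 183 probe sets past the threshold, 97 had no gene name here (67 higher, 30 lower, from -1.49 to 1.94), and the one with the smallest adjusted p of all (0.0049) was among them.

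Doxycycline inhibits mitochondrial translation, which can raise ATF4 targets in treated cells and would lower the difference, no doxycycline minus doxycycline. The median of the ATF4 list had a 95% bootstrap interval over genes of 0.418 to 1.28, so such an effect, if present, was outweighed, which restates the direction and excludes no other action of the drug. The mitochondrial translation list was slightly higher with doxycycline (median difference -0.05, camera adjusted p = 0.103, fry adjusted p = 0.0186). Whether that is an action of the drug was not tested. A shift of genes of that brightness by the normalization is also argued against, since the highest median among 10000 random lists matched on mean expression was 0.175 against 1.03. The ATF4 median exceeded that of the unfolded protein response list by 1.04 (95% bootstrap interval 0.33 to 1.33), a difference outside the rule set beforehand. By that rule, endoplasmic reticulum stress can be neither held nor excluded. The unfolded protein response list had a median of -0.01, but its interval reached 0.522, just above the bound of 0.513 set from the ATF4 median. Only 9 of its 19 listed genes were measured. XBP1 and ERN1 were at 0.52 and 0.53, and the list passed upward in fry (adjusted p = 0.0356). No array separates KDM4C from doxycycline withdrawal, so both stay open, as does a shortage of amino acids in denser cultures, since the labels used here give no cell density.

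Mitosis genes differed from S phase genes by 0.33 in median (95% bootstrap interval over genes 0.18 to 0.47). A larger share of cells in cycle would raise both lists. The S phase median had an upper bound of 0.127, under the bound of 0.186 set from the mitosis median. That argues against the explanation as the whole cause only if S phase genes rise as strongly as the rule assumed, which was not tested. Of 23 S phase genes, 17 had positive differences, and the list passed upward in fry (adjusted p = 0.0356). Brightness is argued against, with a highest random median of 0.188 against 0.37. A larger share of cells in cycle, a larger share in G2 or M, or higher transcription of these genes per cell are candidate explanations. The arrays do not separate them, and KDM4C and doxycycline stay confounded here too.

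A hypothesis drawn from JUN, EGR1, FOS, DUSP6 and SPRY2 was that ERK signalling was higher without doxycycline. A list of ERK pathway feedback genes, without those already seen to pass, had 13 measured members, 9 with positive differences. That 0 were past limma's threshold follows from this removal. The matched random lists were not stripped of passing genes, which tilts the comparison against the hypothesis. Its median of 0.076 (95% bootstrap interval -0.007 to 0.112) was the value of MYC, which with FOSL1 also stood in the fixed lists. Both genes were dim, below the median probe set: MYC at 3.10 without and 3.02 with doxycycline, FOSL1 at 3.76 and 3.67. The list's median lay at percentile 96.9 of 10000 matched random lists, below the upper bound set beforehand, a random-list median of 0.0812. Its interval reached past that bound, so the test neither bears the hypothesis out nor excludes it. SPRY4 and ETV5 were at 0.52 and 0.30.

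The real grouping gave 183 probe sets past the threshold, and the highest count among the other splits of the 6 arrays into 3 and 3 was 0. Only 1 of the 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05. Each other split mixes arrays with and without doxycycline, so the real difference widens the spread within its groups. Low counts there were likely in advance, and the contrast with 183 says little.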
